A study of Nicotiana benthamiana with 9 samples.

How the data were processed

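RNA was measured by sequencing in leaves of Nicotiana benthamiana, a wild relative of tobacco that is widely used for transient expression. Plants were 5 weeks old and grown in soil. There were 9 libraries, 3 in each of 3 groups named in the labels: mock plants kept at 23 °C without a wound for 1 h, heat-treated plants kept at 37 °C for 1 h, and plants wounded with scissors and then kept at 23 °C for 1 h. The series states that the 3 libraries of a group are biological replicates, and it names mock as the control. Total RNA was extracted with Trizol and libraries were made by a sequencing company, per the labels' protocols. The aligner, the counting tool and the genome build are not given in the sources used here.

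The authors deposited 1 table of 56094 rows with 4 values per library. Each row is a whole assembly sequence and not a gene: there are 39565 rows named as scaffolds and 16529 named as contigs, every region starts at 1, every row name equals its chromosome name, and 0 rows carry an identifier. The lengths run from 500 to 2838176 nt with a median of 932 nt and sum to 2969810994 nt. The sequence names begin with Niben101. A deposited count is therefore the number of reads, or read pairs, assigned anywhere on a scaffold or contig, and 1 row of a long scaffold can pool the transcripts of many genes. How reads with several matching places were handled is not given in the sources used here, so sequences that share near-identical copies are uncertain. Strand handling is likewise not given. The deposited RPKM values equal the count divided by the whole sequence length and by the library's total count, and the deposited TPM values are rescaled so that each library sums to 1000000. The authors' columns headed CPM are a scaled signal: within a library they are the count divided by 1 constant, and their sums run from 909725.7 to 1068742, so each library has a scaling factor. Those factors lay between 0.9357 and 1.099, and the TMM factors computed here lay between 0.9285 and 1.092.

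The files do not pair the sequences with genes, and no genome or annotation was used here. The lists of heat shock, jasmonate, ethylene, photosynthesis and cell type marker genes that were fixed before the data were examined match on gene descriptions, so none of them could be applied, and no gene, pathway or cell type is named. The planned rule for this case was followed: per comparison, the 2 sequences that rose most and the 2 that fell most by fitted log2 fold change were named, among those with an adjusted p under 0.05, all 3 treated libraries beyond all 3 control libraries and a mean of at least 10 CPM in the higher group. Length classes were set after the table was seen to hold whole sequences.

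Counts were tested with edgeR 4.0.16 (R 4.3.3) as deposited: sequences with low counts were removed with filterByExpr on the groups, libraries were scaled by TMM, and 1 quasi-likelihood model of the 3 groups was fitted to all 9 libraries. This left 9645 sequences, which held between 99.94% and 99.953% of each library's count. P-values were adjusted by the Benjamini-Hochberg method over the tested sequences, with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM values in the text are counts per 1000000 of the TMM-scaled library size. Where a control group had no count, the fold is a lower bound against a floor of 3 counts per library, between 0.1751 and 0.2295 CPM. Ratios of summed counts carry exact 95% binomial intervals, and shares of sequences carry exact 95% binomial (Clopper-Pearson) intervals. Intervals on counts and floors cover counting error only, because reads without molecular identifiers are not independent molecules. Group shares of the count were compared with two-sided exact permutation tests, for which 3 libraries against 3 cannot give a p below 0.1.

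Total counts ran from 13846165 to 17480792 per library. The common biological coefficient of variation was 15% and the median standard error of a log2 fold change was 0.163 after heat and 0.159 after wounding. The test was tried on simulated data with 200 of the 9645 sequences changed per treatment. A first simulated table, tested without a filter, had 16 unchanged sequences among 148 heat calls (10.8%) and 8 among 137 wounding calls (5.84%), above the share of 0.05 that the threshold aims at. After that result was seen, the number of tables was raised to 10, the first included, and the filter of the real data was added. The pooled values that follow are therefore from the revised check. The heat comparison recovered 36.3% of 1.5-fold, 66.4% of 2-fold and 89.5% of 4-fold changes, and the wounding comparison recovered 33.9%, 71.3% and 88.5%. Unchanged sequences made up 5.75% of the pooled calls for heat and 4.8% for wounding, with single tables between 1.74% and 10.9% for heat. Without the filter the pooled shares were 5.95% and 4.94%. The simulated rises and falls were equal in number. They were also far fewer than the real calls (50.18% of sequences after heat, 14.88% after wounding). These shares and recoveries need not hold for the real comparisons, above all for heat. To allow for the mock libraries that both comparisons share, 100 tables with no treatment effect were simulated and compared in the same way. In all simulated tables a sequence started from its mean in mock, or over all 9 libraries where mock had no count. Sequences with no mock count were therefore simulated as present in mock. After the results had been seen, both treatments were also set against separate mock libraries, 1 for one and the remaining pair for the other, in 6 arrangements of an edgeR model with 4 groups. No 2 libraries were copies of each other, since the chi-square of counts per degree of freedom between replicates was at least 11.7. The replicate numbers did not pair the libraries: of the 9 same-numbered pairs from different groups, 1 had a correlation of deviations above 0.1 (range -0.144 to 0.109).

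The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma 3.58.1 on log2 CPM, no filter and a filter of 10 CPM in 3 libraries, the replicate block, fits of the compared groups alone, each library left out, an adjusted p under 0.01, an added 2-fold minimum, and limma on log2(TPM + 1) and log2(TPM + 0.1) for sequences of at least 1 TPM in 3 libraries. Figures were drawn with matplotlib 3.10.9.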

Results

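Leaf RNA was counted over the assembled scaffolds and contigs of Nicotiana benthamiana in 3 mock, 3 heat-treated and 3 wounded libraries. The study asked which transcripts respond to 1 h at 37 °C and which respond to wounding followed by 1 h at 23 °C. Mock libraries held 15587154, 14821545 and 16326700 counts, heat libraries held 13846165, 14087184 and 17480792, and wounded libraries held 15471362, 14517149 and 15298471. Between 11660 and 11921 sequences had a count in a given library, 16276 had one in any library and 39818 had none in any. Because each value belongs to a whole scaffold or contig, the changes below are those of genomic regions, and a long region can hold several genes that moved in different directions.

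The libraries fell into their 3 groups. Heat libraries separated from the others on the first principal component, which held 67.98% of the variance, with scores of 71.39 to 80.42 against -42.04 to -31 for all mock and wounded libraries. The second component, with 12.95% of the variance, separated mock from wounded libraries. Correlations of log2 CPM across sequences were 0.9785 to 0.9874 within groups, 0.9658 to 0.9742 between mock and wounded libraries and 0.8945 to 0.9093 between heat and mock libraries.

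**Figure D1:**
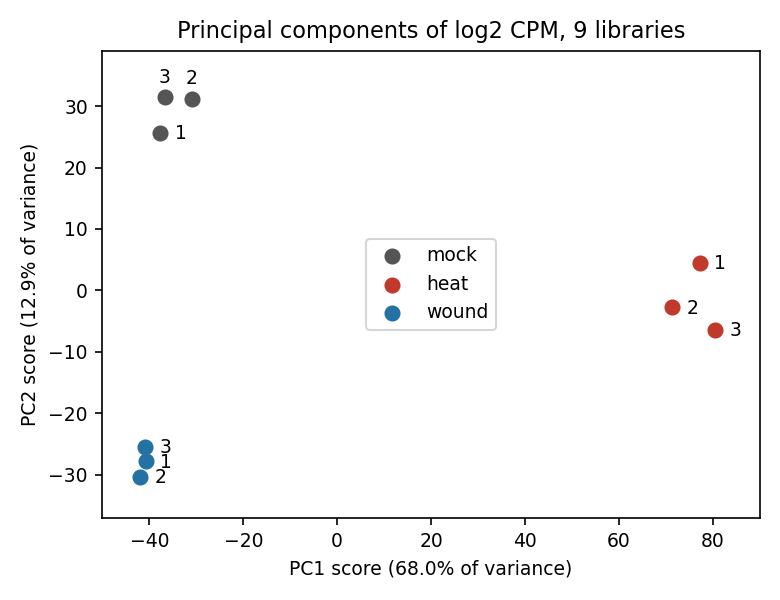
Scores of the 9 libraries on the first (x axis) and second (y axis) principal components of log2 CPM over 9645 sequences; each point is 1 library, labelled with its replicate number and coloured by group. The 3 heat libraries lie above 71 on the first component and the wounded libraries lie between -30.31 and -25.42 on the second.

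Heat changed the read counts of 4840 of 9645 tested sequences (50.18%), of which 2642 rose and 2198 fell. Changes of at least 2-fold were found for 1239 that rose and 828 that fell, and changes of at least 8-fold for 321 and 74 by fitted fold change. A set of 121 sequences had no count in any mock library and at least 10 counts in every heat library, against 9 in the reverse direction. Of these 121, 92 were shorter than 2000 nt and 98 also had no count in any wounded library. Together they carried 1268 ± 98.7 CPM (SD, n = 3) in heat libraries. Counts were tested with edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment. The balance of directions depended on the scaling: upper-quartile factors moved the median log2 fold change to -0.173 and gave 2033 higher and 3191 lower (38.92% higher, against 54.59% with TMM), and library totals alone gave a median of -0.119 with 2126 higher and 2818 lower. For changes of at least 2-fold, upper-quartile factors gave 1013 higher and 1131 lower. Library totals alone gave 1064 and 1022, and RLE factors gave 1219 and 853.

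The contig Niben101Ctg10208 (positions 1 to 1056) came first by fitted fold change among those that rose after heat, an order that depends on the prior count where mock has no count. It had 7097, 8452 and 8804 counts in the heat libraries, or 566 ± 70.3 CPM (SD, n = 3), and no count in any mock library, so it was at least 3060-fold higher (edgeR adjusted p = 4.21e-09). Wounded libraries held 10 counts of it in all. The next was Niben101Scf21159 (positions 1 to 926), a scaffold with 59.6 ± 14.1 CPM after heat and no count in any mock or wounded library. It was at least 323-fold higher than mock (edgeR adjusted p = 7.27e-07).

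Among sequences that fell after heat, Niben101Scf22800 (positions 1 to 67033) dropped from 18.6 ± 8.37 CPM in mock to 0.908 ± 0.426 CPM in heat libraries (SD, n = 3). Its log2 fold change was -4.38 ± 0.395 (SE, edgeR adjusted p = 4.63e-06), while wounded libraries held 18.3 ± 1.53 CPM. Niben101Scf19057 (positions 1 to 50961) dropped from 24.3 ± 20.9 to 1.45 ± 0.609 CPM, a log2 fold change of -4.03 ± 0.665 (SE, edgeR adjusted p = 4.11e-04). Its mock libraries were far apart, with 113, 770 and 307 counts. Without mock replicate 2 the log2 fold change was -3.085 (adjusted p = 4.39e-04), and over all alternatives with a filter the adjusted p was at most 0.0161.

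Wounding changed 1435 of the 9645 sequences (14.88%), of which 951 rose and 484 fell. At least 2-fold changes comprised 348 that rose and 92 that fell. In all, 9 sequences had no count in mock and at least 10 counts in every wounded library. The rise of more sequences than fell was kept by every scaling tried, with the smallest margin under upper-quartile factors (801 higher and 761 lower, 51.28% higher against 66.27% with TMM). The deposited scaling factors gave 987 higher and 474 lower. The counts rested on single libraries more than those of heat: 616 rose and 258 fell without mock replicate 3, 627 and 194 without wound replicate 1, 297 fell without wound replicate 2 and 261 without wound replicate 3.

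The contig Niben101Ctg12548 (positions 1 to 1574) and the scaffold Niben101Scf28036 (positions 1 to 26261) were named among those that rose after wounding, and their order was not established. The contig reached 31.9 ± 8.54 CPM (SD, n = 3), had no count in any mock library and was at least 173-fold higher (edgeR adjusted p = 4.53e-05). Heat libraries held 0.568 ± 0.547 CPM of it. Niben101Scf28036 went from 0.146 ± 0.101 CPM in mock to 38 ± 11.9 CPM in wounded libraries. With 7 mock counts in all, the ratio was 264.1, with a 95% counting interval of 127.9 to 657.9 (edgeR adjusted p = 7.23e-06). Mock replicate 1 held 4 of those counts, and the log2 fold change of 7.97 became 8.6 without it.

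Among the abundant sequences that met the naming rule, 2 were named as falling after wounding, and their order was not established. Niben101Scf08422 (positions 1 to 220293) fell from 746 ± 281 to 159 ± 27.1 CPM (SD, n = 3). The log2 fold change was -2.23 ± 0.259 (SE, edgeR adjusted p = 2.1e-04). Heat libraries held 242 ± 59.2 CPM of it. The contig Niben101Ctg15836 (positions 1 to 5349) fell from 36.2 ± 29.8 to 8.47 ± 1.05 CPM, a log2 fold change of -2.1 ± 0.606 (SE, edgeR adjusted p = 0.0385). That call was lost without mock replicate 2, where the log2 fold change was -1.2 (adjusted p = 0.16), and with the replicate block (adjusted p = 0.0908). It was also lost without mock replicate 3, heat replicate 1 or any of the 3 wounded libraries, with adjusted p between 0.0528 and 0.135, although the log2 fold change stayed between -2.322 and -1.994 there and was -2.01 with the block. Over all alternatives with a filter its adjusted p ran from 0.012 to 0.228.

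**Figure D2:**
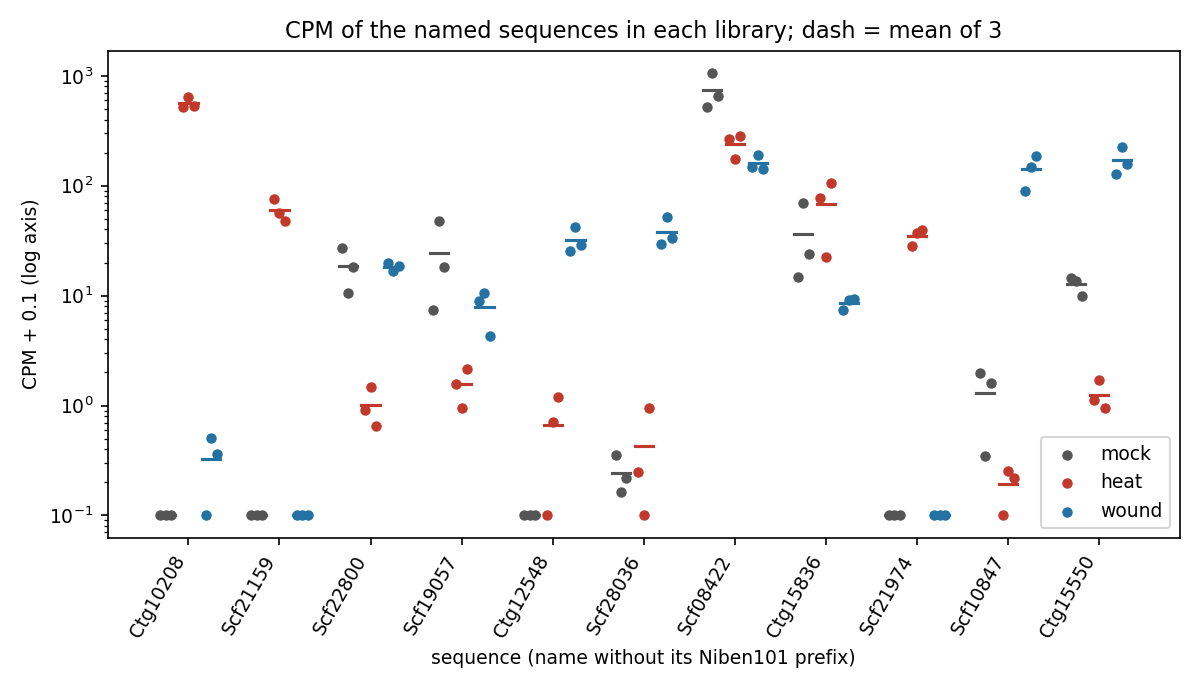
CPM plus 0.1 on a log axis (y axis) of the 11 named sequences (x axis) in each library; points are single libraries coloured by group and dashes are means of 3 libraries. Points at the bottom of the axis are libraries with no count, as in all mock libraries of Niben101Ctg10208, Niben101Scf21159 and Niben101Ctg12548.

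Heat and wounding were then compared directly, which tests whether the responses of a sequence differ since the mock libraries cancel. After heat, 2573 sequences were higher and 2415 were lower than after wounding (51.72% of those tested, edgeR). Of the 2158 sequences that rose after heat and were not called after wounding, 1876 were higher after heat in the direct test. Of the 423 that rose after wounding and were not called after heat, 364 were lower after heat in the direct test. The selection favoured both results, because the direct test reused the same heat and wounded libraries, so they are only descriptive. With upper-quartile factors the direct test gave 2168 higher and 3060 lower, or 41.47% higher against 51.58% with TMM.

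The sequences named as higher after heat than after wounding came first by fitted fold changes over groups with no count, so their rank was not established. Niben101Scf21159 was at least 300-fold higher. Niben101Ctg10208, with 10 wounded counts, had 566 CPM after heat against 0.223 CPM after wounding. Niben101Scf21974 (positions 1 to 781) had 35 ± 5.93 CPM after heat (SD, n = 3) and no count in any mock or wounded library, at least 176-fold higher (edgeR adjusted p = 6.79e-07). In the other direction, Niben101Scf10847 (positions 1 to 89863) had 141.3 ± 48.4 CPM after wounding, 1.21 ± 0.854 CPM in mock and 0.0914 ± 0.0807 CPM after heat. The wounded libraries exceeded the heat libraries by a ratio of 1525, with a 95% counting interval of 595.5 to 5600 on 4 heat counts (edgeR adjusted p = 1.07e-07). The contig Niben101Ctg15550 (positions 1 to 4392) had 170.5 ± 50.5 CPM after wounding, 12.5 ± 2.4 in mock and 1.16 ± 0.397 after heat, and the log2 fold change of heat against wounding was -7.22 ± 0.301 (SE, edgeR adjusted p = 6.8e-09).

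Both treatments raised 376 sequences, or 39.5% of those that rose after wounding, and both lowered 207, or 42.8% of those that fell. Independent lists of these sizes would share 260.5 and 110.3. Opposite directions were called for 260 sequences, where independent lists would give 349.3. The covariance of the log2 fold changes over sequences was 0.187. In 100 simulations with no effect of either treatment against shared mock libraries its mean was 0.04 (0.0335 to 0.0454), a difference of 0.147. The observed value was 0.826 without a filter, 0.0903 with the stricter filter, 0.1247 for sequences of at least 2000 nt (chosen after seeing the data) and 0.3052 without mock replicate 2. The corresponding Pearson r was 0.18 observed and 0.496 simulated, and sequences are not independent replicates. With 1 mock library as the control of one treatment and the remaining mock libraries as that of the other, the covariance was 0.1006 to 0.2006 over the 6 arrangements, where simulations with no effect gave -0.0156 to 0.0158. Shared rises then numbered 95 to 236 and shared falls 30 to 138, above the count for independent lists in each arrangement. The smallest ratio came with 162 rises against 147.5 and 107 falls against 93.1. Counts for independent lists assume that every sequence is equally easy to call, while the share called differed between length classes. Small excesses over them are therefore not shown to exceed chance. A lone mock library was assumed to vary like the other groups. The overlaps fell to 211 and 104 without mock replicate 3, and to 236 and 96 without wound replicate 1. The shared falls fell to 136 without wound replicate 2 and to 117 without wound replicate 3. The balance also depended on the scaling. Upper-quartile factors gave 255 shared rises and 388 shared falls, and library totals alone gave 246 and 279.

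**Figure D3:**
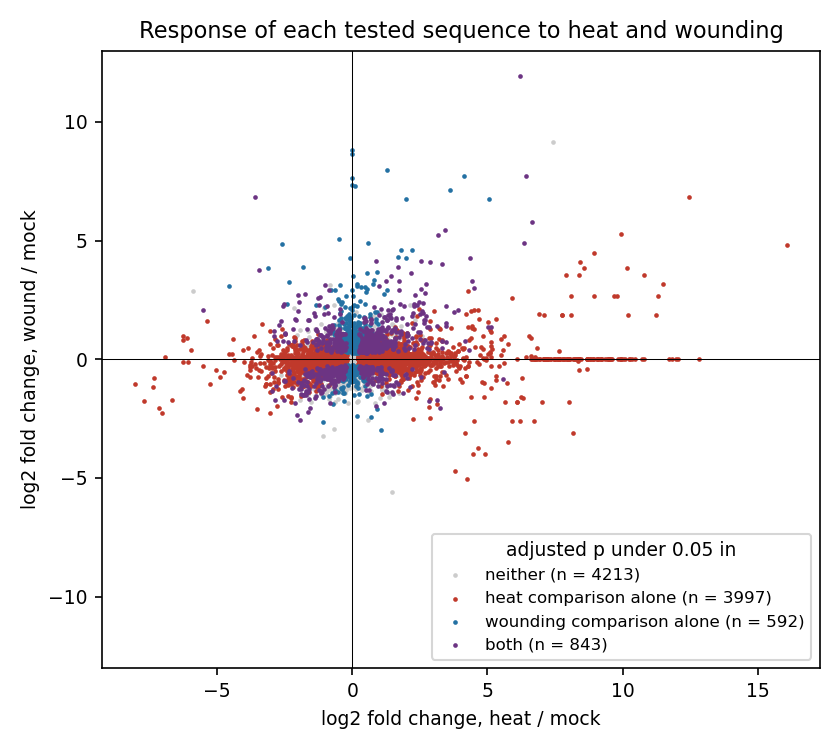
Fitted log2 fold change after heat (x axis) and after wounding (y axis), each against mock, for the 9645 tested sequences; each point is 1 sequence, coloured by the comparison in which it passed an adjusted p of 0.05. The 843 sequences called in both comparisons lie in all 4 quadrants, and the row of points at 0 on the y axis beyond 6 on the x axis holds sequences with no count in mock or wounded libraries.

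Sequence length went with the share of sequences that changed after both treatments, in a direction that depended on the measure. The share called at any size rose with length, from 36.4% under 2000 nt to 55.1% at 200000 nt or more after heat. After wounding it rose from 5.79% to 18.2%. Among sequences with a mean of at least 10 CPM the rise after heat was smaller, from 50.8% to 56.7%. After wounding the share there was 10.9% under 2000 nt and 17.6%, 19.2% and 19.1% in the longer classes. By contrast, changes of at least 2-fold were least frequent in the longest class. Of the 1243 tested sequences under 2000 nt, 31.2% (28.6% to 33.9%, exact 95% interval) changed at least 2-fold after heat, against 15.3% (14.3% to 16.4%) of the 4724 scaffolds of 200000 nt or more. The odds of such a change in the longest class were 0.484 times those of all other sequences (0.436 to 0.535, two-sided Fisher's exact test, adjusted p = 2.71e-45 over 24 tests). After wounding, 4.99% of the shortest and 3.49% of the longest class changed at least 2-fold. The odds ratio against all other sequences after wounding was 0.611 in the longest class (0.499 to 0.748, adjusted p = 1.3e-06), 1.37 from 20000 nt to under 200000 nt (1.12 to 1.68, adjusted p = 0.00337) and 1.54 from 2000 nt to under 20000 nt (1.12 to 2.1, adjusted p = 0.00848). In the shortest class it was 1.11 (0.832 to 1.47, adjusted p = 0.442). These tests and intervals treat sequences of the same libraries as independent, so they do not measure variation between plants. Median depth differed between the classes, at 1.65 CPM for the shortest and 66.7 CPM for the longest. Heat counts also helped decide which sequences were tested. Of the sequences under 2000 nt, 92 had no count in mock and at least 10 counts in every heat library. Such sequences raise the share of the shortest class after heat.

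**Figure D4:**
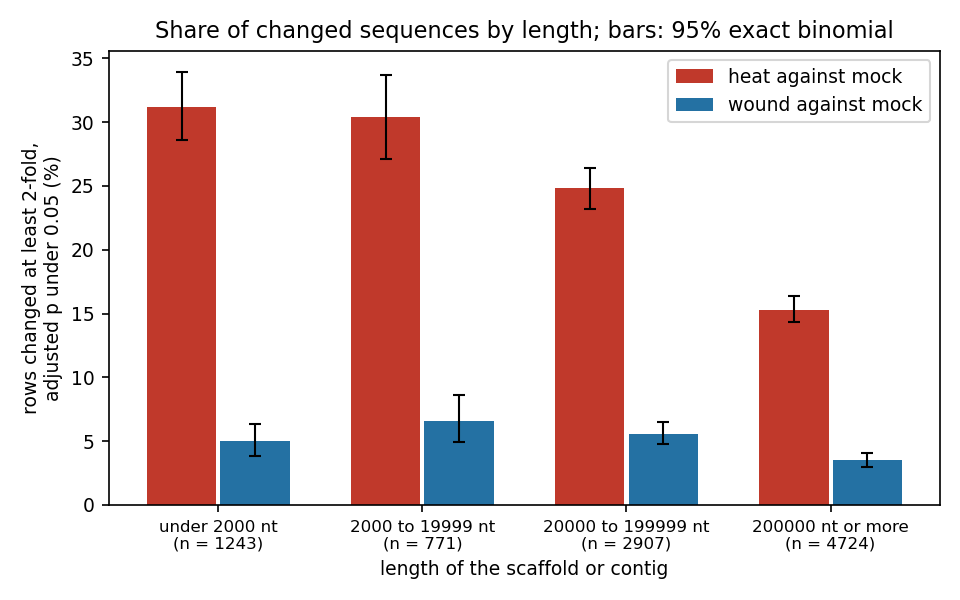
Percentage of tested sequences called and changed at least 2-fold (y axis) in 4 classes of sequence length (x axis, number of sequences in parentheses), for heat and for wounding against mock; error bars are exact 95% binomial intervals. The share after heat goes from 31.2% in the shortest class to 15.3% in the longest.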

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

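The deposited scaling factors, library totals alone and a restriction to sequences of at least 2000 nt were chosen after seeing the data; the other alternatives were planned. Planned tests of gene lists and marker lists could not be run, since the table names no genes. No call of the 6 lists against mock or between treatments changed to the opposite direction under the 24 settings tried. Among the 12 named results, 11 stayed past an adjusted p of 0.05 wherever they were tested, and Niben101Ctg15836 after wounding lost its call in 10 of 22 settings. The p-values of the fit without a filter were far smaller than those of the others, as for Niben101Scf19057 after heat (adjusted p 8.77e-53 against 4.11e-04), and that setting is weak evidence that a call holds. Adding a 2-fold minimum left 1239 and 828 sequences higher and lower after heat, 348 and 92 after wounding, 1237 and 937 between treatments, and 94 and 35 shared. An adjusted p under 0.01 left 511 and 141 after wounding and 158 and 60 shared. Limma on log2(TPM + 1) gave 220 and 94 after wounding, 57 and 60 shared, and 1360 lower after heat than after wounding; with a pseudocount of 0.1 these were 224, 98, 61, 58 and 1398. The sequences lower after wounding numbered 761 with upper-quartile factors and 756 with DESeq2, and the shared falls numbered 388 and 315. Library totals alone left 246 shared rises. The covariance of the responses was 0.826 without a filter, 0.0903 with the stricter filter and 0.1247 for sequences of at least 2000 nt. The cause of these shifts was not tested, apart from the thresholds, which remove calls by construction. Leaving out 1 library at a time gave 616 to 1118 rises and 194 to 606 falls after wounding, 211 to 442 shared rises, 96 to 226 shared falls and a covariance of 0.1816 to 0.3052. The replicate numbers share only a number: 2 of the 9 libraries correlated best with their own number. With the replicate block, 2492 rose and 1999 fell after heat and 765 and 332 after wounding. In the simulated tables the heat test recovered 95.2% of 2-fold changes in sequences of at least 10 CPM and 19.6% below that, where the median dispersion was also higher (0.0717 against 0.0129), so depth and dispersion were not separated. A sequence that was not called is not shown to be unchanged.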

Other observations

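The tests of direction and of count share by class, the class of abundant sequences, the covariance at 10 CPM or more the length test with depth taken from mock and wounded libraries and the fits with separate mock libraries were chosen after results had been seen. Direction after heat differed between classes of sequence. The Fisher's exact tests in this section treat sequences as independent, so their p-values do not measure variation between plants. From 2000 nt to under 20000 nt, 92 rose and 142 fell at least 2-fold, against 1147 and 686 of all others (two-sided Fisher's exact test, adjusted p = 2.21e-10 over 14 tests). Their median log2 fold change was -0.198, and they stayed more often lower than the rest under RLE, upper-quartile and unscaled totals (adjusted p at most 9.61e-07). Their share of the count was 2.31% ± 0.0714 in mock and 1.56% ± 0.0724 in heat libraries (SD, n = 3, exact permutation p = 0.1, the smallest that 3 against 3 can give). After wounding this class also had fewer rises for its falls than the others (33 and 18 against 315 and 74, adjusted p = 0.0206). Scaffolds of 200000 nt or more leaned the other way after heat, with 504 that rose and 221 that fell at least 2-fold (adjusted p = 3.93e-10), and after wounding, with 145 and 20 (adjusted p = 0.00116). Under upper-quartile factors 384 of them rose and 331 fell after heat. Contigs as a class leaned downward, with 163 that rose and 200 that fell at least 2-fold after heat (adjusted p = 7.46e-10, and at most 1.76e-07 under the other scalings), and their share of the count was 4.3% ± 0.372 in mock and 3.42% ± 0.15 in heat libraries (exact permutation p = 0.1). Each contig also belongs to a length class, and contigs were not tested within those classes. Their lean is therefore not shown to be separate from that of length. The contig Niben101Ctg10718 alone held 1.7% ± 0.26 of the count in mock and 1.46% ± 0.138 in heat libraries.

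The 129 most abundant sequences, those with a mean share of at least 0.1% of the count, comprised 14 that rose, 38 that fell and 77 not called after heat. At least 2-fold, 7 rose and 7 fell, and this balance was not shown to differ from that of the other sequences (two-sided Fisher's exact test, adjusted p = 0.631 over 14 tests, and 0.687 to 0.716 under the other scalings). Falls of any size outnumbered rises among them under all 4 scalings (12 rose and 60 fell with upper-quartile factors, and 12 and 64 with unscaled totals, so that most were then called). They held 39.4% ± 2.89 of the count in mock, 32.9% ± 2.11 in heat and 38.7% ± 1.04 in wounded libraries (SD, n = 3). After wounding 5 of them rose and 1 fell, and with unscaled totals 5 rose and 6 fell. The contig Niben101Ctg10718 (positions 1 to 1137, named after its values were seen) took 37.99% to 49.51% of all TPM but 1.304% to 2.117% of the count, because TPM here divides by whole sequence length.

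The larger share of short sequences that changed at least 2-fold after heat was weighed first. Counting noise would leave no excess among well-covered sequences, yet with a mean of at least 10 CPM the odds of a 2-fold call were 2.83 times higher under 2000 nt than at 200000 nt or more (1.87 to 4.2, 128 and 4267 sequences, two-sided Fisher's exact test). Heat counts helped decide that limit. With the limit set on the mean of mock and wounded libraries alone the odds ratio was 2.34 (1.5 to 3.55, 124 and 4249 sequences), which argues against noise as the whole cause. Depth was not matched in that test, with medians of 19.9 CPM for the short and 72.8 CPM for the long sequences under the limit without heat. Summing of several transcribed loci on long scaffolds stays open. When random sets of 10 short sequences were summed, a median of 15.3% of the sums changed at least 2-fold (9.68% to 21% over 20 draws), against 31.2% for single short and 15.3% for long sequences. Summing unrelated sequences lowers this share whatever the cause, and the set size was a free choice, so the test decides nothing. The true number of transcribed loci per scaffold was not known here. Counting per gene would test this, and no biological explanation was tested.

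Far more sequences were counted in every heat library and in no mock library than the reverse (121 against 9). Deeper heat libraries were argued against by the total counts. Heat replicates 1 and 2 held 13846165 and 14087184 counts, fewer than any mock library (14821545 to 16326700). Heat replicate 3 held more (17480792). Thinning each library to 13846165 counts gave 118 and 5. It left heat replicate 1 unchanged and could only add zeros in mock, so it adds little. What the heat treatment does to transcription stays open, as untested, and so do reads placed on near-identical copies elsewhere in the assembly, because no sequence was used here.

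Heat and wounding moved more sequences in the same direction than independent lists would, a count that assumes every sequence is equally easy to call. The mock libraries shared by both comparisons were argued against as the whole cause, since the covariance of 0.1873 lay above the highest of 100 simulations with no effect (0.0454). For the 6407 sequences of at least 10 CPM the covariance was 0.0674 against a highest simulated 0.0156. With separate mock libraries for each treatment the covariance stayed between 0.1006 and 0.2006 over the 6 arrangements, above the highest of 100 simulations (0.0158). For sequences of at least 10 CPM it was between 0.0145 and 0.0868 (highest simulated 0.00303). The simulations held no treatment effect, so in each of these comparisons their range is narrower than unrelated responses of the observed size would give. The lowest value, 0.0145, is therefore not shown to exceed chance. A response common to both treatments stays open, as untested, and so does any day, position or handling that set the mock plants apart.

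Other splits of the libraries were fitted for each count. Every comparison of 3 against 3 has 10 splits, too few for a share under 0.05, and 1 split, the real one, gave as many calls in each case. The highest of the other splits was 0 against 2642 and 2198 after heat, 1 against 951 and 484 after wounding, and 0 against 2573 and 2415 between the treatments. Each other split put libraries of both real groups on both sides. A difference between the real groups then added to the spread within the sides, which left few calls by construction. These low counts therefore do not test chance. For the shared calls, 2 of 100 assignments of the 9 libraries to 3 groups gave 376 or more rises and 3 of 100 gave 207 or more falls, the real one included. Of the 99 other assignments, 96 gave no shared call in either direction. The shares of 2 and 3 in 100 therefore do not test whether the sharing of calls exceeds chance. The highest others, 1401 and 1888, came from an assignment with the 3 heat libraries as the control and with mock and wounded libraries mixed in both other groups. Another kept all 3 real groups, with the wounded libraries as the control, and gave 243 and 562. Those were 243 of the 484 sequences higher in mock than in wounded libraries, and 562 of the 951 lower. A control group used by both lists can thus give many shared calls where the other groups have no treatment in common. The assignment that called several times the real count compared both other groups with heat libraries, so both of its lists held the heat effect by construction, and the structure of the samples that it shows is the heat group.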
